A study of Mus musculus with 2 samples.

How the data were processed

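Per the labels, chromatin accessibility was mapped by DNase-seq, in which nuclei are treated with the nuclease DNase I and the positions of its cuts are sequenced, in lung of female B6CASTF1/J mice at 4 days of age. B6CASTF1/J is the first-generation hybrid of C57BL/6J and CAST/EiJ mice. The 2 libraries form a single group of 2 biological replicates: replicate 1 came from the animal numbered 6 and replicate 2 from the animal numbered 5. The labels give both animals the same donor record, which stands for the strain, and the separate animal numbers were taken to mark separate mice.

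The authors aligned reads to mm10 (GRCm38), per the labels, and called peaks and footprints for each library on its own from its filtered alignments, per the text deposited beside the files. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. Each library has 2 deposited peak lists, whose signal column holds the authors' signal for each peak. This deposited signal is scaled to the library: all values (100% in each library, within 0.05 of a step) were whole multiples of a step of 0.00459 in replicate 1 and 0.00336 in replicate 2. If signal is a count of cuts per 1000000, the libraries hold about 218000000 and 298000000 cuts, but the scale is not given in the sources used here, so signals are printed as deposited, the SDs over libraries include any difference in scale, and the shifts of gene lists are taken relative to the median difference. A deposited file of false discovery rates (FDR, a q-value for the local cut rate made by the authors) lists short intervals under an FDR of 0.05. All peaks of the longer list but 1 in replicate 2 touched an interval below 0.05 (the highest of the lowest FDR per peak was 0.0499 in replicate 1 and 0.0498 in replicate 2), and all peaks of the shorter list touched one below 0.001, so the longer list was read as the list at 0.05 and used throughout, with the shorter list as an alternative. The deposited footprint files carry a constant p-value or FDR column of 0.01, read as the authors' threshold, so footprints could not be ranked.

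Every chromosome end in the files lay within the GRCm38 length of that chromosome. Coordinates are GRCm38, counted from 1. Genes and transcription starts were taken from GENCODE vM21 (basic set), which held 21827 protein-coding genes on the chromosomes used. Mitochondrial DNA and unplaced sequences were not analysed here. Reads from the CAST/EiJ genome carry variants against the reference used for alignment, and the effect of these on signal was not tested. Overlaps were computed with bedtools 2.31.1 and Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), and plots with matplotlib 3.10.9. Peaks or footprints were shared if they overlapped by at least 1 bp. The chance level came from 20 random placements of all peaks on their own chromosomes, starting at 3 Mb. Footprint chance overlap came from moving each footprint that lay inside merged peaks to a random place of the same merged peak. A promoter peak lay within 500 bp of an annotated transcription start. Other peaks were exonic, intronic or between genes by their midpoint.

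A gene was called accessible if both libraries had a peak within 500 bp of any of its protein-coding transcription starts, and its promoter signal was that of its highest such peak. The 22 gene lists (236 genes, all matched), the 30 motifs and the rule for named genes were fixed before the data were examined. Named genes are, per list, up to 4 members with the highest mean promoter signal and up to 2 members with no promoter peak in either library, the 15 genes with most distal peaks, the 10 promoters with the highest mean signal, and the 10 peaks in each direction with the largest signal ratio between libraries in the upper part of the signal range. A few genes that this rule names are not reported here. Further members were named after their values were seen. Lists were compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists, and with 10000 random lists matched on the CpG ratio (observed over expected CpG) of the promoter window. Genes are not independent replicates, so these tests describe the genes of these libraries and do not measure variation between mice. Shared distal peaks were assigned to the nearest protein-coding transcription start within 100 kb, and list means were set against random lists matched on the distance to neighbouring starts. Shared peaks of all positions were assigned in the same way, and the shift of a list between animals is the median over its genes of the mean log2 signal ratio of shared peaks, minus the median of all shared peaks, set against 10000 random lists matched on mean signal.

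Motif matches to a consensus on either strand were counted per kb in footprints found in both libraries and in the peak sequence outside any footprint. A match was placed by its centre. Ratios carry an exact conditional 95% interval, which covers counting error only. With 1 group of 2 animals, no test between conditions was possible, and values over libraries are given as mean ± SD (n = 2), where the 2 values measure the spread between these samples alone. A peak had a median signal of 132 steps in replicate 1 and 151 in replicate 2. If a step is a single cut, counting alone gives a median error of 0.15 for a log2 ratio, and the observed ratios had an SD of 0.50, so counts set a lower limit to the error of a single peak.

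The functions were tested on simulated data. With peaks made to overlap at 70.7%, the overlap step returned 70.7% over 174653 peaks. The list test called 87% of 100 simulated lists drawn at a 95% share, and 6% of 100 lists drawn at the background share (5% expected). These calls used an unadjusted p under 0.05 and a background share below the 67.3% of the data. The 87% is therefore not the power of the adjusted tests reported here. A planted AP-1 motif at a ratio of 22.3 was returned as 21.5, and 0 of 19 other motifs had an interval away from 1. The simulated sequence had the same base composition in and outside footprints, unlike the data, so it cannot show false calls that come from GC content. Alternatives were a reciprocal overlap of 50%, peaks in the upper part of the signal range, the shorter peak list, a promoter window of 1000 bp, each library left out in turn, matching on CpG ratio, distal peaks within 50 kb, shuffled footprint sequence and footprints away from promoters.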

Results

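Accessible chromatin was compared between the lungs of 2 female mice of 4 days of age. The series has no second tissue, age or treatment, so the comparisons are between the animals, between gene groups and between parts of the genome. Replicate 1 had 174713 peaks and replicate 2 had 158602, each covering 32.2 Mb, with a median width of 180 and 200 bp and a median signal of 0.606 and 0.507.

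Most accessible regions of one animal were also found in the other. Of the peaks of replicate 1, 71.6% overlapped a peak of replicate 2, and 78.1% the other way round (mean 74.9 ± 4.57%, SD, n = 2), against 2.57% for peaks placed at random. Strong regions were shared far more than weak ones: in the lowest decile by signal 18.8% of replicate 1 peaks and 29.3% of replicate 2 peaks were shared, and in the highest decile 99.2% and 99.8%. In replicate 1, 49553 peaks had no counterpart, and in replicate 2, 34723.

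Peak heights followed each other closely. Across 125160 shared peaks the log2 signals had a Pearson r of 0.945 and a Spearman rho of 0.916, taken across peaks, which are not independent replicates. Signal was higher in replicate 1 by a median of 1.32-fold (log2 0.40), and the ratios had an SD of 0.50 on the log2 scale against a median counting error of 0.15 if a step of the signal is a single cut. Of the shared peaks, 4.82% lay more than 2-fold from the median ratio.

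**Figure D1:**
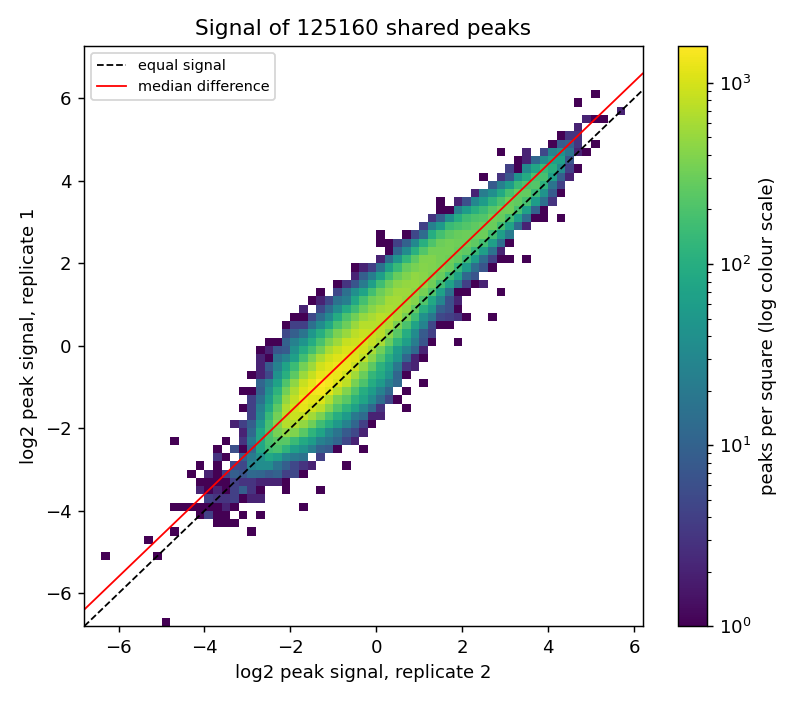
Log2 peak signal of the 125160 shared peaks, replicate 2 on the horizontal and replicate 1 on the vertical axis, with colour for the number of peaks per square on a log scale. The solid line marks the median difference of 0.40, and the dashed line equal signal.

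Among the stronger shared peaks, the largest excess in replicate 2 at promoters lay at Ncf4, a subunit of the phagocyte NADPH oxidase (signal 0.478 in replicate 1 and 1.53 in replicate 2), and at Fgfr1op (0.785 and 2.27). A peak 15076 bp from the start of Cd47, which encodes a cell surface signal that restrains phagocytosis, had 0.404 and 1.51. Other peaks higher in replicate 2 were nearest to Tmem196 (2.37 and 7.64), Prss22 (0.381 and 1.16) and Iffo2 (0.441 and 1.31), and a pair lay far from any gene on chromosomes 8 and 12. Peaks higher in replicate 1 included one 8458 bp from C1qa, which encodes a chain of complement C1q (3.80 and 0.706), and others nearest to Rgs22 (2.36 and 0.383), Hcrtr2 (1.84 and 0.302), Vwde (1.58 and 0.269), Epha7 (2.03 and 0.346), Adamts3 (1.35 and 0.232) and Nrg2 (1.42 and 0.262), with a further pair far from genes on chromosomes 3 and 7. Peaks near Gm11168 and Gm10718, at the start of the sequenced part of chromosome 9, differed in both directions (6.84 and 1.08 at one Gm11168 peak, 1.71 and 6.83 at another), and their place is uncertain, as is that of the peaks at the start (3109801) and end (120028681, nearest to Tmem196) of the covered part of chromosome 12. With 1 library per animal, differences of this kind hold animal and library together.

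Accessible regions were concentrated at promoters. Peaks within 500 bp of a transcription start made up 17.8 ± 0.307% of all peaks (SD, n = 2), against 2.77% at random places. Introns held 43.3% (43.0% at random), exons 5.86% (3.33%) and the space between genes 33.1% (50.9%). Promoter peaks were also stronger, with a median signal of 1.71 and 1.48 in the 2 libraries against 0.537 and 0.454 elsewhere, which is 3.19-fold and 3.27-fold. Between animals, 84.5% and 90.4% of promoter peaks were shared, against 68.9% and 75.4% of the others. The promoter share was 27.3% in the stronger peaks alone, over 1.5 times the share in all.

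Of 21827 protein-coding genes, 14694 (67.3%) had a promoter peak in both libraries. The share was 96.8% for promoters with a CpG ratio of 0.6 or more and 37.1% for those below, so each gene list was also set against random lists of matched CpG ratio.

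Genes of the alveolar epithelium were accessible throughout. All 12 genes of the alveolar type 2 list, whose cells make surfactant, had a promoter peak in both animals (adjusted p = 0.0188, Fisher's exact test over 22 lists; 0.00147 against CpG-matched lists by permutation). Signals were highest at Cebpa, a transcription factor of the C/EBP family (17.5 in replicate 1 and 12.5 in replicate 2), Etv5, an ETS factor (13.6 ± 1.12, mean ± SD, n = 2), Abca3, the lipid transporter of lamellar bodies (10.9 ± 1.36), and Lpcat1, an enzyme of surfactant lipid synthesis (7.92 ± 2.59). The surfactant protein genes had lower signals: Sftpb 1.74, Sftpc 1.72, Sftpd 0.750 and Sftpa1 0.650. Their promoters also had lower CpG ratios (0.165 to 0.248) than those of the leading genes (0.764 to 0.923), so signals were not ranked at equal CpG content. For scale, CpG-rich autosomal promoters accessible in both animals had a median signal of 7.51. The median of the list was 1.73. All 12 genes of the alveolar type 1 list, for the flat cells of gas exchange, were accessible as well (exact adjusted p = 0.0188; CpG-matched permutation adjusted p = 0.0510), led by Vegfa (9.07 ± 3.72), Rtkn2 (8.32 ± 3.31), Cav1, the coat protein of caveolae (5.26 ± 1.11), and Hopx (5.00 ± 1.37). The transcription factors of the lung epithelium were accessible in 12 of 12 cases (exact adjusted p = 0.0188; CpG-matched permutation adjusted p = 0.694), with Klf5 at 7.58 ± 0.498, Irx2 at 4.00 ± 0.408, Gata6 at 3.32 ± 0.231 and Foxp2 at 2.70 ± 0.744. With the shorter peak list the calls of the type 2 and transcription factor lists ended (91.7% each, exact adjusted p = 0.0866).

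Of 12 genes of secretory, ciliated and basal cells, 5 were accessible (exact adjusted p = 0.0796). The members with the highest signal were Rsph1, a part of the radial spoke of motile cilia (20.4 ± 4.03), Foxj1, the regulator of motile ciliogenesis (13.1 ± 1.02), Tppp3 (11.4 ± 0.448) and Ccdc39 (1.62 ± 0.468). The cadherin gene Cdhr3 and the axonemal dynein gene Dnah5 had no promoter peak in either library. Nor did Scgb3a1, Scgb3a2 or Krt5, of the secretory and basal members. Scgb1a1 had one in replicate 2 alone and Trp63 in replicate 1 alone, which left Cyp2f2 as the only secretory or basal member accessible in both. Of 6 neuroendocrine genes, 5 were accessible (exact adjusted p = 0.703), among them Chga, which encodes chromogranin A (4.08 ± 3.06), Syp (1.80 ± 0.294), Uchl1 (0.775 ± 0.112) and Calca (0.702 ± 0.105), while Resp18 had no peak. CpG-matched lists had a median of 41.7% for the airway list (41.7% accessible) and 100% for the neuroendocrine list (83.3%), and neither list passed against them.

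Vessel and stromal genes were accessible almost without exception. All 14 endothelial genes had a peak in both animals (exact adjusted p = 0.0147; CpG-matched permutation adjusted p = 0.0044), with Esam at 5.53 ± 1.28, Egfl7 at 3.40 ± 0.876, Kdr, a receptor for VEGF, at 3.33 ± 1.37 and the tight junction gene Cldn5 at 2.51 ± 0.254. Of 14 fibroblast and mesenchyme genes 13 did (exact adjusted p = 0.0559; CpG-matched permutation adjusted p = 0.0044), led by the matrix genes Fn1 (6.93 ± 1.83) and Eln, which encodes elastin (6.19 ± 1.35), the growth factor receptor gene Pdgfra (5.90 ± 1.79) and Foxf1 (3.20 ± 0.550). All 10 smooth muscle and pericyte genes did (exact adjusted p = 0.0474; CpG-matched permutation adjusted p = 0.0170), led by the myosin gene Myh11 (6.71 ± 2.97), Tagln (2.49 ± 0.142), Notch3 (2.23 ± 0.965) and Lmod1 (2.20 ± 0.331). Of 6 mesothelial genes 2 did, Wt1 (0.466 ± 0.0940) and Upk1b (0.385 ± 0.0461), and Gpm6a and Lrrn4 did not (exact adjusted p = 0.103). That share of 33.3% equalled the median of CpG-matched lists, which were drawn for the main setting alone. The endothelial call ended with the shorter list (85.7%, exact adjusted p = 0.123) and with the stronger peaks alone (71.4%, exact adjusted p = 0.614), the fibroblast list passed without replicate 1 (100%, exact adjusted p = 0.0154), the smooth muscle call ended with a 1000 bp window (exact adjusted p = 0.0547), and with the stronger peaks or the shorter list 0% of the mesothelial genes was accessible (exact adjusted p = 0.00827 and 0.00562).

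Blood cell genes were accessible in both animals less frequently than other genes, a difference that did not pass against CpG-matched lists. Of 14 macrophage and neutrophil genes, 4 had a promoter peak in both animals (exact adjusted p = 0.00752; CpG-matched permutation adjusted p = 0.998): Cd68 (1.79 ± 0.481), S100a8 (1.66 ± 0.285), the lysozyme gene Lyz2 (1.02 ± 0.188) and Itgax (0.512 ± 0.308), while Mrc1 and Ptprc had none in either. This list differed between the animals more than any other, with 28.6% of its promoters accessible in replicate 1 and 85.7% in replicate 2. Of 10 lymphoid genes 0 were accessible in both (exact adjusted p = 0.000101; CpG-matched permutation adjusted p = 0.168), with no peak at Cd3d, and of 8 erythroid genes 1 was (exact adjusted p = 0.00624; CpG-matched permutation adjusted p = 1), with none at Alas2 or Epb42. Without replicate 1 the macrophage and neutrophil list turned to 85.7%, above the other genes (exact adjusted p = 0.275), and with a 1000 bp window it was 42.9% (exact adjusted p = 0.0601).

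Genes of the cell cycle and housekeeping genes were accessible in 10 of 10 cases each (exact adjusted p = 0.0474; with a 1000 bp window 0.0547). Ccna2 (13.9 ± 0.557), Birc5 (12.9 ± 2.20), Cdk1 (11.4 ± 0.0230) and Bub1 (9.47 ± 3.08) led the first, and Rplp0 (20.5 ± 1.35), Ppia (18.4 ± 2.28), Polr2a (14.2 ± 2.41) and Actb (13.5 ± 1.69) the second. Neither list passed against CpG-matched lists (permutation adjusted p = 1 for each).

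Genes of most other tissues were closed. Liver genes had no promoter peak in either animal (0 of 12, exact adjusted p = 3.24e-05), Ahsg and Alb among them, nor did 8 of the 10 retina genes, Crx and Gnat1 among them (0 accessible in both, exact adjusted p = 0.000101). Of 12 pancreas and intestine genes 1 was accessible, Cela1 (0.698 ± 0.201), and Cdx1 and Cdx2 had no peak (exact adjusted p = 0.000209). In the lists of heart muscle, germ cell and kidney genes 1 of 10 was accessible in each (exact adjusted p = 0.00094), among them Ryr2 of the heart list (1.75 ± 0.699) and Dazl of the germ cell list (8.17 ± 0.834), with no peak at Myh6, Myh7, Acrv1, Ddx4, Aqp2 or Nphs1. Of 10 skeletal muscle genes 2 were, Mylpf (10.8 ± 3.60) and Actn3 (0.611 ± 0.0132), and Ckm and Myf5 were not (exact adjusted p = 0.0072; 0.0876 with a 1000 bp window). Neuronal genes were the exception, at 8 of 12 (exact adjusted p = 1), including Grin1 (2.21 ± 1.21), Camk2a (1.18 ± 0.486), Slc17a7 (0.948 ± 0.186) and Tubb3 (0.749 ± 0.142), with none at Neurod1 or Neurod2. Their share of 66.7% was not high for their CpG content, since CpG-matched lists had a median of 83.3% (permutation adjusted p = 0.266). With the stronger peaks alone it was 33.3% (exact adjusted p = 0.0872). Against CpG-matched lists, 3 of the lists stayed below (pancreas and intestine, germ cell, retina). Without replicate 2 the heart muscle, germ cell and kidney lists stood at 20% each (exact adjusted p = 0.00493). Pancreas and intestine stood at 16.7% (0.0014) and skeletal muscle at 30% (0.0242), so these lists stayed below the other genes.

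The lists from alveolar type 2 to macrophage and neutrophil were counted as lung. Of their members, 89 of 112 (79.5%) and 14 of 86 genes of other tissues (16.3%) had an accessible promoter in both animals, an odds ratio of 19.9 (95% interval 9.06 to 44.6; p = 1.26e-19, two-sided Fisher's exact test across genes). The odds ratio was 30.9 without replicate 1, in which 4 of the 14 macrophage and neutrophil genes were accessible.

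**Figure D2:**
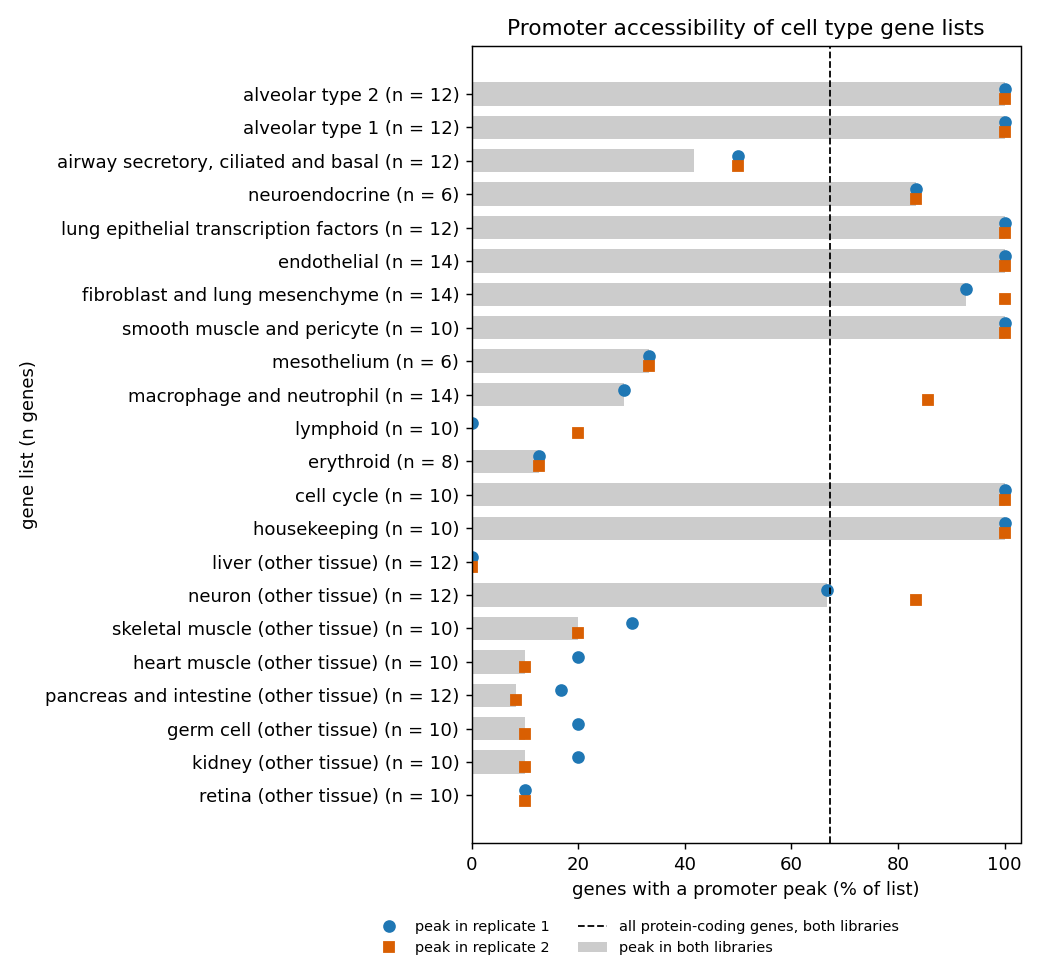
Percent of genes with a promoter peak, by list: bars show peaks in both libraries, circles replicate 1, squares replicate 2 and the dashed line all protein-coding genes (67.3%). The macrophage and neutrophil list differs most between animals, 28.6% against 85.7%.

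The strongest promoter of all was that of Dynlt1b, a dynein light chain gene (54.4 ± 1.36, n = 2), which has near-identical neighbours, so its place is uncertain. Next came Hjurp, the chaperone that loads the centromeric histone CENP-A (44.0 ± 4.94), Nup107, of the nuclear pore (36.6 ± 10.2), the peak shared by Mplkip and Sugct (33.7 ± 8.79), Myo10 (30.3 ± 5.68), Fzr1, an activator of the anaphase-promoting complex (29.7 ± 5.39), the translation factor gene Eif5a (28.2 ± 4.56), Rragc (28.1 ± 5.53) and Hivep3 (28.0 ± 6.32).

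Distal accessible regions were unevenly spread over genes. Tns1, which encodes the focal adhesion protein tensin 1, had most (67 shared distal peaks), followed by Pde4d (58), the forkhead factor gene Foxp1 (57), Mecom (53), and Bach2 and Bcor (52 each). Cacna1c and Smad7, an inhibitor of TGF-beta signalling, had 49 each, Sept9 and Sh3pxd2a 48, Zfp423 47, Frmd4a and Irf2bp2 46, and Rara, a retinoic acid receptor gene, 45. The median gene had 2, and 80995 of 99211 shared distal peaks (81.6%) lay within 100 kb of a gene. This ranking was not adjusted for gene length or for the distance to other genes. Pde4d is 1299 kb long, with 699 kb to the next protein-coding start. For Tns1 these values were 214 and 17.7 kb. Among members of the lung lists, named after their values were seen, Foxa2 had 28, Tbx5 27, Col1a1 25, Grhl2 24, Gata6 23 and Cdh5 21. Endothelial genes had a mean of 11.2 against 5.29 in random lists (permutation adjusted p = 0.0616), epithelial transcription factors 13.5 against 7.08, fibroblast genes 12.1 against 6.57, smooth muscle and pericyte genes 6.0 against 2.8 and housekeeping genes 5.4 against 2.4 (permutation adjusted p = 0.0739 each), and 0 of the 22 lists passed. Counting all distal peaks within 50 kb of a gene, in place of assigning each to the nearest gene, left 6 of the 15 genes in the top 15, and leaving out replicate 1 left 9.

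Footprints, short stretches protected from cutting, were shared less than peaks. Replicate 1 had 447073 and replicate 2 had 459497, of which 52.7% and 52.4% overlapped one of the other library (mean 52.5 ± 0.235%, SD, n = 2). Of those inside peaks 52.8% did, against 35.7% after moving each within its peak. Peaks held 86.9% of footprints, 84.6% of peaks had at least 1, and 27.7% of footprints lay at promoters.

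Footprints found in both animals marked several promoters of lung genes, chosen after their values were seen. At Sftpc, which encodes surfactant protein C, the promoter peak at chromosome 14, 70524121 to 70524420 (signal 1.72 ± 0.225), held footprints at 70524153 to 70524173 (TCTGCCAGCCAAGTCCTTGGC) and 70524237 to 70524255 (CCCAAGGGCCCTTGGCCTA), neither with the centre of a match to any of the 30 motifs. At Hopx, the footprint at chromosome 5, 77115190 to 77115212 (CCAGCTTCCTTATTTGGACTCGG), held an SRF match. SRF matches had a density ratio of 1.12 in all shared footprints against flanking peak sequence, and its interval (0.968 to 1.295) includes 1. A match alone thus does not show that the factor was bound. At Etv5, the footprint at chromosome 16, 22439671 to 22439693 (CCGCCATTGGCCCGCAGCCCAGA), held an NFY match.

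**Figure D3:**
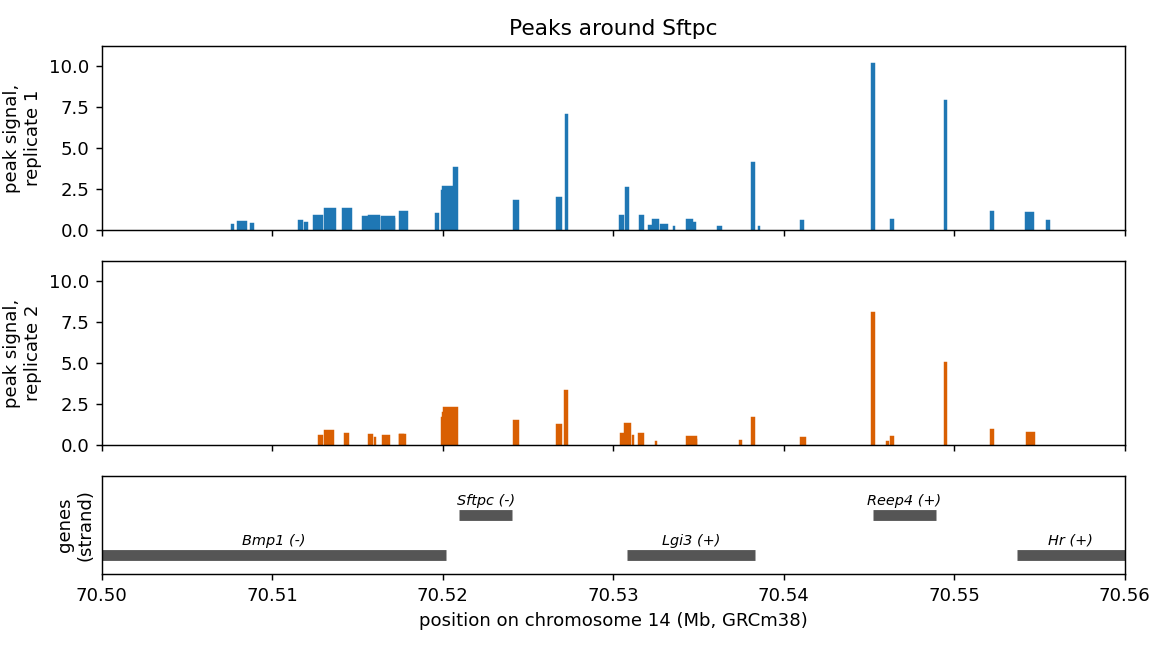
Peaks around Sftpc on chromosome 14 (position in Mb, GRCm38): bars show the extent and signal of each peak in replicate 1 (top) and replicate 2 (middle), with genes and strands at the bottom. The Sftpc promoter peak has a signal of 1.87 in replicate 1 and 1.56 in replicate 2.

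Motifs of several factors were concentrated in footprints. Matches to CTCF, the insulator protein, were 112 times as dense in shared footprints as in the surrounding peak sequence (95% interval 101 to 123), those of NRF1 168 times (107 to 277), and those of REST, a repressor of neuronal genes, 1156 times, with 148 matches against 1 (204 to 45981). RFX stood at 28.1, with 18 matches against 5 (10.1 to 96.9). NFI stood at 23.0 (17.5 to 30.6), CRE at 19.5 (17.2 to 22.1), KLF/SP at 16.3 (15.6 to 17.0), C/EBP at 10.7, YY1 at 9.49 and ETS at 8.10. The motif of NKX2-1, a regulator of lung epithelium, stood at 1.22 (1.07 to 1.39), with 1.48 away from promoters and 0.518 at promoters. Footprints were richer in GC (61.6%) than the flanking peak sequence (52.995%). In all, 15 of 30 motifs had an interval above 1 and 11 below (18 and 2 against shuffled footprint sequence), the 11 including FOX (0.267), p53 (0.422), GATA (0.447) and AP-1 (0.476). Away from transcription starts the ratio was 45.9 for NRF1, 10.97 for CRE, 9.14 for KLF/SP, 2.65 for ETS and 1.07 for NFY (1.66 in all shared footprints). Against shuffled footprint sequence it was 45.0 for NRF1, 9.69 for KLF/SP and 3.37 for C/EBP, but 51.2 for CRE and 22.8 for ETS. YY1 stood at 174 in that comparison, with an interval of 30.8 to 6912, so its size is poorly known. TEAD, RUNX, MEF2, POU5F1, IRF and STAT turned from below 1 to above it (1.47, 1.57, 4.79, 1.54, 2.23 and 1.28), while FOX (1.06), AP-1 (0.909), GATA (0.814) and ZEB (0.991) no longer differed from 1.

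**Figure D4:**
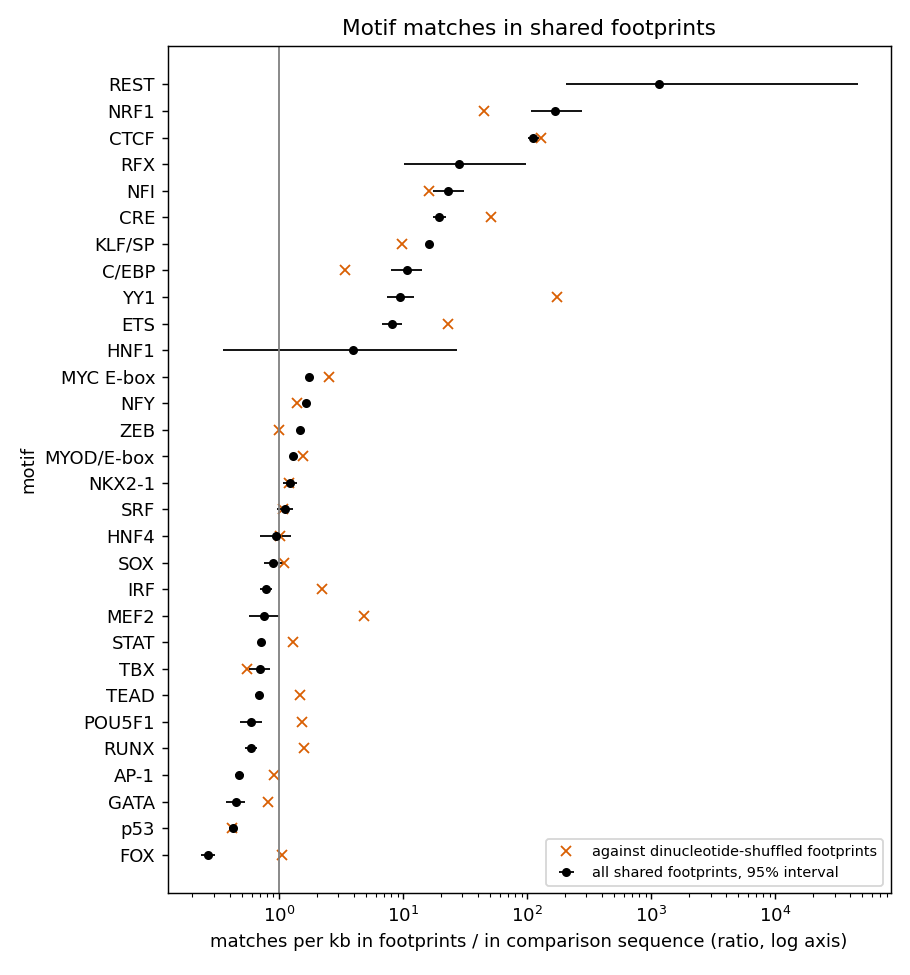
Ratio of motif matches per kb in shared footprints to those in flanking peak sequence, on a log axis, with exact 95% intervals (counting error only); crosses show the ratio against shuffled footprints. Against flanking sequence CTCF (112), NRF1 (168) and REST (1156) lie highest; against shuffled footprints NRF1 has 45.0.

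Chromosome X was less accessible than every autosome in both animals. It had 28.3 and 23.4 peaks per Mb, against 55.1 to 106 and 49.1 to 98.0 on the autosomes, a ratio to the median autosome of 0.377 ± 0.0223 (SD, n = 2). The median peak signal was lower too, at a ratio of 0.674 ± 0.0324, and so was that of promoters, at 0.433 ± 0.00665. Promoter peaks were found at 52.4% of X genes and 70.5% of autosomal genes. These animals carry a pair of X chromosomes, of which one is silenced in each cell. No test was made across chromosomes, and with the stronger peaks alone the density ratio was 0.261.

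**Figure D5:**
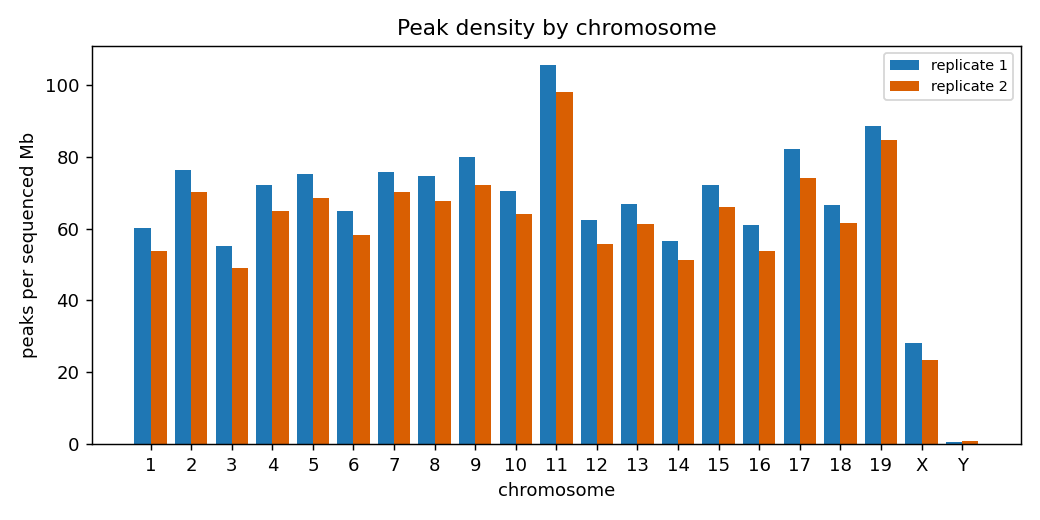
Peaks per sequenced Mb on each chromosome in replicate 1 and replicate 2, 1 bar per library. Chromosome X, at 28.3 and 23.4, lies below all autosomes, the lowest of which has 55.1 and 49.1.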

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

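Of the tests below, those on deeper sequencing and on cells of all blood lineages, and the matching on GC content as an alternative, were chosen after the result was seen, and the bound for cells of all blood lineages was made stricter after its value was known. The shifts of gene lists between animals were not among the comparisons planned at the start.

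Peaks on chromosome Y were found in libraries from female mice, outside the comparisons of the report: 60 in replicate 1 and 70 in replicate 2, with a median signal of 0.181 and 0.143. Male tissue in the samples is argued against by the promoters of Ddx3y, Eif2s3y, Kdm5d and Uty, 0 of which had a peak in either library. A candidate explanation is sequence shared with other places: 58.8% of the 36-base windows of these peaks recur exactly in the genome and 40.8% outside chromosome Y, against 0.474% in peaks of chromosome 1. Apart from male tissue, no biological explanation was tested, since the design holds a single group.

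Genes of macrophages and neutrophils had more signal in replicate 2, by a median of -0.43 on the log2 scale relative to all shared peaks (replicate 1 over replicate 2, 0.744-fold, 63 peaks, higher in replicate 1 in 4 of 14 genes; permutation p = 0.0002, the smallest these can give, adjusted p = 0.0022), and 8 of their promoters had a peak in replicate 2 alone and 0 in replicate 1 alone (exact sign test p = 0.0078, which fails correction at an adjusted p of 0.172; 7 of the 8 have no overlapping peak in replicate 1, while that of Spi1 overlaps one outside the promoter window). A signal-to-noise difference that follows mean signal is argued against as the whole cause. Without adjustment, 7 lists lay outside the central 95% of random lists matched on signal, and 3 had an adjusted p under 0.05. GC content bias is argued against likewise, since the macrophage and neutrophil list stayed at percentile 0 among lists matched on GC content as well. Matching of this kind leaves other differences between the libraries in place. Deeper sequencing of replicate 2 would give it most promoters found in 1 library only, and it had 44.9% of 788 (exact 95% interval 41.4 to 48.5). Replicate 1 had more peaks, however (174713 against 158602), which could offset a gain from depth, so this share cannot decide the question. More cells of all blood lineages could not be settled: the lymphoid and erythroid lists lay at percentiles of 95.4 and 99.1, towards replicate 1, but on 6 and 11 peaks, and Cd79a and Cd8a had promoter peaks in replicate 2 alone. The shift did not cover the whole list. Lyz2 (-0.88), Siglecf (-0.81) and Spi1 (-0.70) were among the members towards replicate 2. The 4 towards replicate 1 were S100a9 (0.52), Adgre1 (0.08), Csf3r (0.03) and Mrc1 (0.02). A different share of some myeloid cells in the tissue taken may be the source, but animal and library cannot be separated with 1 library per animal.

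Promoters on chromosome X had a median signal of 0.433 times that of autosomes. Fewer CpG-rich promoters on X are argued against as the whole cause, since among CpG-rich promoters alone the ratio was 0.513 ± 0.0247 (SD, n = 2). Silencing of 1 X chromosome is a candidate explanation: Kdm6a (21.8 ± 1.38), Kdm5c (11.7 ± 1.66), Ddx3x (8.56 ± 1.11) and Eif2s3x (7.11 ± 0.878), genes known to escape it, had a median of 10.1, above the 1.26 to 6.64 of random lists of CpG-rich X promoters (percentile 99.99). The median of these escape genes also exceeded the 7.51 of accessible CpG-rich autosomal promoters, so escape alone need not account for their height. The random lists were not matched on how widely genes are active, so the rank cannot tell escape from broad activity. Silencing remains a hypothesis, since no male lung was analysed here.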

How the results depend on the processing

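The alternatives with CpG-poor or CpG-rich promoters alone and with matching on GC content were chosen after seeing the data. With a reciprocal overlap of 50%, shared peaks were 64.1% and shared footprints 38.5%. With the stronger peaks alone, shared peaks were 95.3%, r was 0.925, the promoter share was 27.3% and the X ratio 0.261. The promoter share was 23.3% with a 1000 bp window and 23.7% with the shorter list. Lists above the other genes numbered 4 with a 1000 bp window, 4 with the shorter list and 4 against CpG-matched lists, in place of 7, and lists below numbered 3 against CpG-matched lists in place of 10. Leaving out a replicate gave 28.6 to 85.7% for the macrophage and neutrophil list, which turned above the other genes without replicate 1 (85.7%). Of the 15 genes with most distal peaks, 6 stayed when all distal peaks within 50 kb of a gene were counted in place of nearest-gene assignment, and 9 to 12 with a replicate left out. Against shuffled footprints, 6 motifs turned: TEAD 1.47, RUNX 1.57, MEF2 4.79, POU5F1 1.54, IRF 2.23 and STAT 1.28. The cause was not tested in these cases, apart from the stricter settings, which keep the stronger peaks by construction. The odds ratio of lung against other-tissue genes stayed above 1 under all alternatives run (13.5 to 30.9; CpG-poor promoters 20.4), and among CpG-rich promoters, where 36 of 36 lung genes and 7 of 17 others were accessible, it had no finite value, and X stayed at 0.361 to 0.393 with a replicate left out. With GC matching, which changes the random lists and not the shifts, 22 of 22 lists stayed on the same side of the threshold. A stricter footprint score was not run, since the score is constant, and RFX, REST and HNF1 gave no shuffled value. No paired analysis was possible because there is 1 group. In the lowest decile by signal 18.8% and 29.3% of peaks were shared; whether depth sets this was not tested.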

Other observations

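The comparison of CpG-rich genes of other tissues with all CpG-rich genes, and the choice of promoters found in 1 library, were tests chosen after the results were seen. The shifts of gene lists between animals were not planned at the start either.

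Of promoters with a peak in 1 library and no overlapping peak in the other, the strongest in replicate 2 were those of Slc11a1, a metal transporter of phagosomes (signal 1.16), C130050O18Rik (1.05), Hal, the first enzyme of histidine breakdown (0.921), and the receptor genes Cd300a (0.911) and P2ry6 (0.776). The strongest in replicate 1 were those of Lancl2 (4.25), Cln8 (3.52), Rimbp3 (1.67), the T-box factor gene Tbx6 (1.26) and Ankrd24 (1.19), and a peak of the other library just outside the promoter window is not excluded by this measure. There were 338 such promoters in replicate 2 and 422 in replicate 1, and no theme was tested over them.

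Other lists differed between animals as well, relative to all shared peaks. The median over liver genes lay towards replicate 1 (log2 0.61, 1.52-fold, 6 of 8 genes, 33 peaks, permutation adjusted p = 0.0022), although 0 of 12 liver promoters had a peak. Apoa1, which held 15 of these peaks, went the other way (-0.17), as did Cyp2e1 (-0.21), so the median over genes does not describe the peaks as a set. Neuronal genes also had a median towards replicate 1 (log2 0.29, 11 of 12 genes, permutation adjusted p = 0.0484). Endothelial genes stood at log2 -0.17, erythroid genes at 0.37 and germ cell genes at 0.32 (permutation adjusted p = 0.0667 each), which fail the threshold. Of the 8 lists of other tissues, 7 had a median towards replicate 1, with retina at 0.28, pancreas and intestine at 0.21 and kidney at 0.21, and liver and neuron alone passed.

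The authors' intervals under an FDR of 0.05 covered 52692684 bp in replicate 1 and 52692022 bp in replicate 2, a difference of 662 bp, yet shared 41.7 Mb, 65.4% of their union.

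A hypothesis was that promoters of other-tissue genes are open in lung where they are CpG-rich, whatever the tissue. Of CpG-rich members 41.2% were accessible (7 of 17, exact 95% interval 18.4 to 67.1) and of the others 10.1% (7 of 69; p = 0.00533, Fisher's exact test), so CpG content went with accessibility. The share did not reach the 50% set in advance, nor fall to that of the other members, so the criteria set in advance left it open. It lay below the 96.9% of all other CpG-rich genes, which argues against CpG content as the whole cause.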
